A study of Felis catus with 23 samples.

How the data were processed

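MicroRNAs (miRNAs) were measured in serum from 11 cats with hypertrophic cardiomyopathy (HCM, a thickening of the heart muscle) and 12 healthy cats, 1 array per cat. Per the labels, blood clotted for 20 min and was spun at 600 g for 5 min, and the serum was kept at -80 °C. Total RNA was isolated with Qiazol and the miRNeasy Mini kit and labelled with Cy3 with an Agilent miRNA labelling kit. The arrays were an Agilent 1-colour design for human miRNAs, which also holds probes for miRNAs of human viruses. Each array held 62944 spots, of which 60780 belonged to 4944 probes for 2026 miRNA names, 1887 human and 139 viral. A probe had between 7 and 30 spots. No cat genome and no probe sequences were used here, so no genome positions are given and no probe was matched to a cat miRNA. Every miRNA name below is the human or viral name of a probe.

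Per the file headers, the scanner files hold spot brightness as intensity on a linear scale, made by Agilent Feature Extraction 10.7.3.1, with background already subtracted in the processed signal and no normalization between arrays. They also hold flags of 0 or 1 for each spot, which per the file headers carry other information than brightness. The deposited series table of the authors holds log2 values for 1758 probes, of which 1750 are miRNA probes with 965 names. Those log2 values were checked against the processed signals: over probes above an intensity of 8, the correlation per array was between 0.987 and 0.9998 and the slope between 0.950 and 0.980. Their direction and log base were thus settled from the data, but the normalization behind them is not stated and stays unknown. The median of the deposited log2 values for HCM replicates 1, 2, 3 and 5 to 12 was, in this order, 3.26, 3.15, 3.18, 3.18, 3.17, 3.19, 3.30, 3.20, 3.275, 3.12 and 3.195. For healthy replicates 14 to 23, 25 and 26 it was 3.15, 2.98, 3.295, 3.23, 3.12, 3.25, 3.30, 3.26, 3.31, 3.235, 3.30 and 3.125.

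The main values were computed from the scanner files. Control spots and spots marked as outliers by the scanner software (between 1.81% and 3.95% of the miRNA spots of an array) were left out, and the processed signals of the remaining spots of a probe were averaged. A probe counted as detected on an array when at least 50% of its spots were well above background in the scanner's own call. Each array was scaled to its 75th percentile over the 508 probes detected on all 23 arrays, because only 18.6% of all probe values were detected. Scaled values were floored at 5.45, the 5th percentile of the scaled signals that were well above background, and log2 transformed, which puts the floor at 2.45. Each miRNA was represented by its probe with the highest mean over the 23 arrays, chosen without regard to group. A miRNA was tested when that probe was detected on at least 6 of 23 arrays, which left 543 names, 504 human and 39 viral. The number of arrays limits the precision of every value.

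HCM was compared with healthy by limma 3.58.1 (lmFit and eBayes, 2-sided) in R 4.3.3, without covariates, and p was adjusted by the Benjamini-Hochberg method over the tested names. The threshold was an adjusted p of 0.05. A fit with slide as a block was run beside it. Lists of miRNAs with at least 3 tested members were compared with the other tested miRNAs by camera at a correlation of 0.01, with an estimated correlation beside it, and adjusted over the lists. The lists were also tested by fry, which compares a list with no change and not with other miRNAs. The lists were the circulating heart failure and hypertrophy, fibrosis, red cell, platelet, leukocyte, endothelium and vessel wall, miR-17 clusters, DLK1-DIO3, miR-320, and GC-rich or fragment-prone lists. The myomiR list (miRNAs enriched in muscle), the liver list and the let-7 list had too few tested members. Measures of array quality were compared by 2-sided permutation tests of the difference in means with 100000 resamples, and within each slide by exact permutation. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures.

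The samples, groups, main test, lists, named miRNAs and most alternatives were chosen before the data were examined. The rule for the named miRNAs was the following. Of miRNAs past the threshold, the 10 with the largest positive and the 10 with the largest negative difference would be named. Where fewer than 5 passed in a direction, the ones with the smallest p in that direction were added up to 5 and given as values. Tested members of a fixed panel of 21 miRNAs were named, of which those under detection were only counted. For each list, up to 4 members with the smallest p were named. Any miRNA detected on at least 9 arrays of one group and at most 2 of the other would be named as well, and 0 met this.

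The limma fit and the list test were tried on simulated data with 543 miRNAs and these group sizes in 20 runs. For the recovery rates, 40 miRNAs were changed at each size. Known differences were added to the finished main values, with group means removed and arrays shuffled. Scaling, floor, detection filter and probe choice were thus not tested. No added difference was cut at the floor, so recovery may be overstated for names near it. The limma fit recovered 34% of differences of 0.5 on the log2 scale, 82.25% of differences of 1 and 98.25% of differences of 2. Of its calls, 4.35% were false, and the mean bias of a recovered difference was 0.0039. When only 5 miRNAs were changed by 1 on the log2 scale, it recovered 53%. Without any change, 1 of 20 runs made a call. A list of 20 miRNAs, the GC-rich or fragment-prone list with every member shifted by 1, was called in 20 of 20 runs. The other lists tested had between 3 and 9 members, and smaller shifts were not tried. The result thus says nothing on recovery for those lists or shifts. False calls of the list test were not simulated.

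The alternatives tried were the 75th percentile over all probes, quantile normalization, no scaling, normexp background correction with an offset of 50, the deposited values, a floor at the 1st or the 20th percentile, the mean of a miRNA's probes, the total gene signal of the scanner software, no detection filter, a filter for detection on all arrays, slide as a block, each slide alone, array quality weights, a mean-variance trend with robust eBayes, a permutation rank test per miRNA, and leaving out each array in turn. The normexp alternative had been planned on the mean spot signal, which the scanner files do not hold, so the median spot signal was used in its place. Alternatives chosen after seeing the data were a covariate for the array's signal, leaving out the 4 arrays that detected fewest miRNAs, a Fisher's exact test on detection, every deposited probe tested alone, human names only, slide as a block for the array measures, and an estimated correlation wherever another alternative called a list.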

Results

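Serum miRNAs were measured on 23 arrays, 11 from cats with HCM and 12 from healthy cats. The arrays sat on 3 slides, each with both groups. Slide 1 held 3 HCM and 4 healthy arrays, and slides 2 and 3 each held 4 HCM and 4 healthy arrays. On every slide the HCM arrays were in row 1 and the healthy arrays in row 2, so the row of the slide and the group cannot be told apart. Each slide was scanned once, and all scans fell on 1 day.

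An array detected between 322 and 608 miRNA names, and its 75th percentile intensity over the scaling probes lay between 90.5 and 699. Of the 2026 names, 270 were detected on all arrays. No saturated spot was found (0 on each array). The pairwise correlation of arrays over the tested miRNAs lay between 0.834 and 0.974, with a median of 0.936 within groups and 0.938 between groups. Of the 139 names of human viruses, 39 were detected on at least 6 arrays, a share of 28.1%, beside 26.7% of the human names.

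The array-level measures addressed whether sample quality differed between groups. HCM arrays detected 496 ± 67.0 names (SD, n = 11) and healthy arrays 449 ± 89.5 (SD, n = 12), with a permutation p of 0.179 and an adjusted p of 0.394 over 8 measures. The log2 75th percentile intensity was 8.22 ± 0.49 in HCM and 7.80 ± 0.91 in healthy arrays, with a permutation p of 0.187. The log2 difference between miR-451a and miR-23a-3p, which serves as a measure of haemolysis, was -1.45 ± 1.32 in HCM and -0.58 ± 1.75 in healthy serum, with a permutation p of 0.197. Negative control spots read 0.44 in HCM and 0.30 in healthy arrays (permutation p 0.611). The local background intensity was 21.4 and 20.6 (permutation p 0.347). The labelling spike gave a log2 signal of 8.65 in HCM and 9.14 in healthy arrays (permutation p 0.304), and the hybridization spike 14.27 and 14.39 (permutation p 0.318). The bright corner spots gave 10.79 ± 0.76 in HCM and 9.90 ± 1.07 in healthy arrays on the log2 scale, with a permutation p of 0.0341 and an adjusted p of 0.273. Their difference was 0.22 on slide 1, 1.19 on slide 2 and 1.08 on slide 3. Of the 8 measures, 0 differed past the adjusted threshold. With slide as a block and the groups permuted within slides, a test chosen after seeing the data, 0 of 8 passed as well. There the local background was higher in HCM by 0.898 (permutation p 0.0116, adjusted p 0.0930), with differences of 1.13, 0.43 and 1.17 on slides 1, 2 and 3. The negative control spots were higher by 0.219 (permutation p 0.0443, adjusted p 0.118), with differences of 0.54, 0.23 and -0.065, and the bright corner spots by 0.86 (permutation p 0.0394, adjusted p 0.118).

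**Figure D1:**
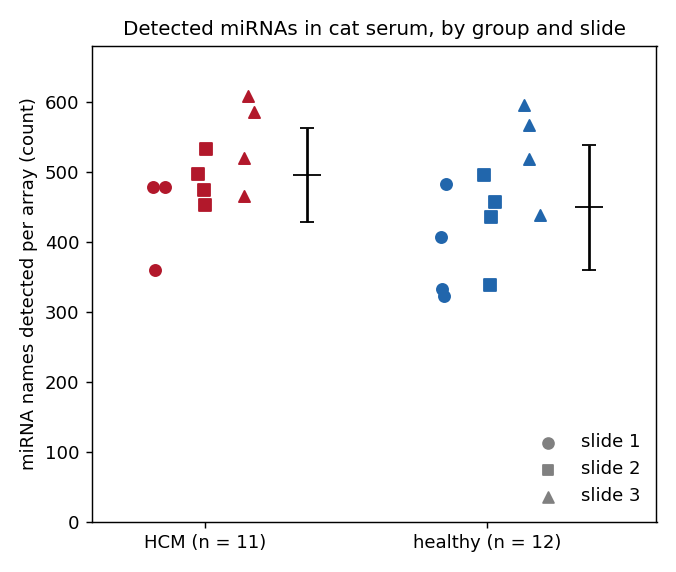
Number of miRNA names detected on each array (count), by group, with symbols for the 3 slides and bars for the mean ± SD. The arrays lie between 322 and 608 names, and the groups overlap.

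The main comparison, HCM against healthy, asked which serum miRNAs differ in cats with hypertrophic cardiomyopathy, the question that the series title states. With limma, 0 of the 543 tested miRNAs passed an adjusted p of 0.05, and the lowest adjusted p was 0.238. At an unadjusted p under 0.05 there were 36 miRNAs, 20 higher and 16 lower in HCM, where chance alone would give 27.15 of 543. With slide as a block, 0 passed, 44 had an unadjusted p under 0.05, and the lowest adjusted p was 0.305. The median difference of all tested miRNAs was -0.10 on the log2 scale and the median standard error 0.22. Absolute differences of at least 1 on the log2 scale were seen for 2 miRNAs, miR-1246 and miR-513a-3p.

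The count depended on the values and the test used. On the log2 values deposited by the authors, the same limma test called 4 miRNAs, all higher in HCM. These were miR-381-3p with a difference of 1.38 (adjusted p 0.0114), miR-4751 with 1.06 (adjusted p 0.0233), miR-5700 with 1.001 (adjusted p 0.0233) and miR-513a-3p with 1.13 (adjusted p 0.0321). On the scanner's total gene signal it also called 4, namely miR-381-3p with 1.57 (adjusted p 0.00863), miR-5700 with 1.85 (adjusted p 0.00863), miR-376c-3p with 1.62 (adjusted p 0.0201) and miR-4751 with 1.53 (adjusted p 0.0204). A permutation rank test on the main values called 1, miR-381-3p, at an adjusted p of 0.0380. A lower floor also called miR-381-3p alone, with a difference of 1.18 (adjusted p 0.0234).

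**Figure D2:**
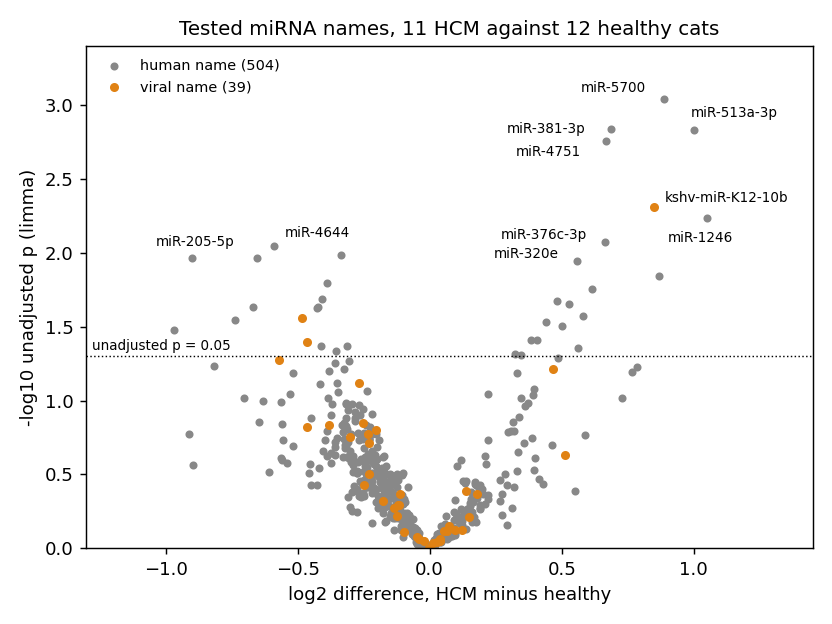
Difference of each of the 543 tested names (log2, HCM minus healthy) against -log10 of its unadjusted limma p, human names in grey and viral names in orange. The dotted line marks an unadjusted p of 0.05, which 36 names passed, while 0 passed after adjustment.

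The 5 names with the smallest p among those higher in HCM follow, none past the threshold in the main values. The log2 value of miR-5700 was 3.65 ± 0.71 in HCM and 2.76 ± 0.43 in healthy serum (SD, n = 11 and 12), a difference of 0.89 (SE 0.24, p 0.00091, adjusted p 0.238). It lay above the healthy median on 10 of 11 HCM arrays and was detected on 10 HCM and 3 healthy arrays. Detection was called before scaling, so such counts also depend on the brightness of the array. Healthy replicates 22 and 25 read 3.19 and 3.37 without detection, while HCM replicate 10 read 2.83 with it. miR-381-3p read 3.13 ± 0.66 in HCM, while all 12 healthy arrays were at the floor of 2.45, a difference of 0.69 (SE 0.19, p 0.00146, adjusted p 0.238). The size of that difference is set by the floor and was 1.18 with a lower one. This miRNA was above the healthy median on 9 of 11 HCM arrays and was detected on 8 HCM and 2 healthy arrays. miR-513a-3p read 6.43 ± 0.67 in HCM and 5.43 ± 0.73 in healthy serum, a difference of 1.001 (SE 0.28, p 0.00148, adjusted p 0.238), above the healthy median on 10 of 11 HCM arrays. miR-4751 read 3.19 ± 0.61 in HCM and 2.52 ± 0.22 in healthy serum, a difference of 0.67 (SE 0.19, p 0.00176, adjusted p 0.238). It was above the healthy median on 8 of 11 HCM arrays and was detected on 8 HCM arrays and 1 healthy array. The viral name kshv-miR-K12-10b read 5.46 ± 0.88 in HCM and 4.61 ± 0.46 in healthy serum, a difference of 0.85 (SE 0.28, p 0.0049, adjusted p 0.516), above the healthy median on 9 of 11 HCM arrays. After normexp the differences of miR-5700, miR-381-3p and miR-4751, which were near the floor, had the opposite sign.

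Among names lower in HCM, the 5 with the smallest p were also short of the threshold. miR-4644 read 7.18 ± 0.53 in HCM and 7.77 ± 0.47 in healthy serum, a difference of -0.59 (p 0.0090, adjusted p 0.516), below the healthy median on 9 of 11 HCM arrays. miR-4515 read 4.51 ± 0.17 and 4.84 ± 0.28, a difference of -0.34 (p 0.0103, adjusted p 0.516), below the healthy median on 11 of 11 HCM arrays. Without scaling between arrays its difference was 0.08. miR-205-5p read 4.28 ± 0.99 and 5.17 ± 0.65, a difference of -0.90 (p 0.0109, adjusted p 0.516), and miR-4476 read 5.26 ± 0.43 and 5.91 ± 0.70, a difference of -0.65 (p 0.0109, adjusted p 0.516). Both were below the healthy median on 10 of 11 HCM arrays. miR-3680-3p differed by -0.39 (p 0.0161, adjusted p 0.614) and was below the healthy median on 10 of 11 HCM arrays. It was detected on 9 HCM and 9 healthy arrays, and a second detected probe for it gave -0.15. Without detection, healthy replicates 20, 22 and 25 read 3.84, 3.69 and 3.69, and HCM replicates 2 and 8 read 3.23 and 3.05. Those healthy arrays were dim, with 75th percentile intensities of 90.5, 104 and 101, so scaling raised their undetected signal.

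Within slides 1, 2 and 3 the difference of miR-5700 was 0.39, 1.52 and 0.74, and that of miR-513a-3p 0.45, 1.92 and 0.62. For miR-381-3p it was 0.86, 0.48 and 0.76, for miR-4751 0.34, 1.02 and 0.60, and for kshv-miR-K12-10b 0.81, 1.46 and 0.28. The differences of miR-4644 within these slides were -0.28, -1.22 and -0.18, those of miR-4515 -0.37, -0.18 and -0.47, and those of miR-205-5p -0.39, -1.61 and -0.54. For miR-4476 the slides gave -0.42, -0.62 and -0.93, and for miR-3680-3p -0.24, -0.52 and -0.39. The direction was the same on the 3 slides for each of these 10 names, which their choice by the smallest p over the same arrays favours. On slide 2 alone, limma called miR-513a-3p (adjusted p 0.0150) and miR-5700 (adjusted p 0.0183).

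**Figure D3:**
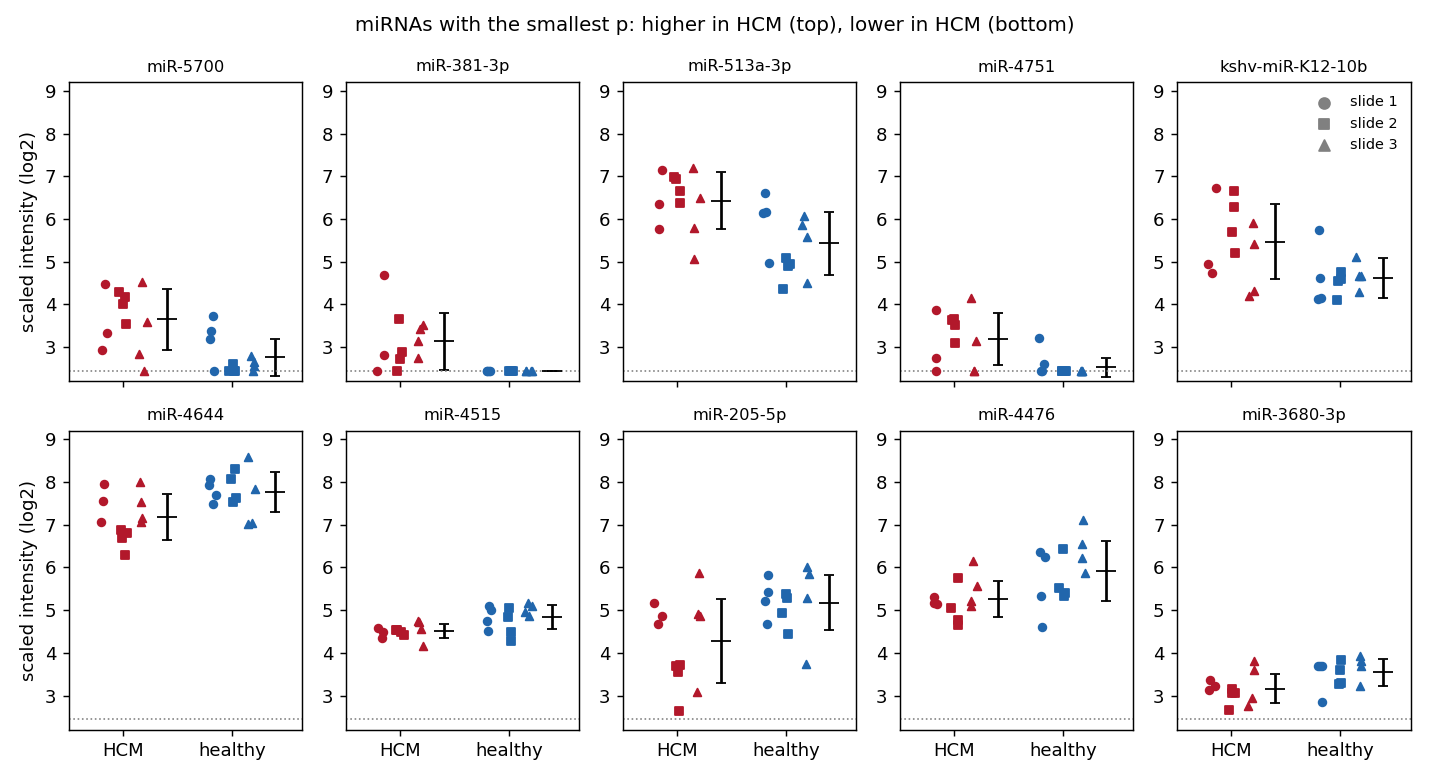
Scaled log2 intensity of the 5 names with the smallest p higher in HCM (top) and lower in HCM (bottom) on each array, with symbols for the slides, bars for the mean ± SD and a dotted line at the floor of 2.45. The healthy values of miR-381-3p all lie at the floor, and after normexp the differences of miR-5700, miR-381-3p and miR-4751 had the opposite sign, as did that of miR-4515 without scaling.

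Of the fixed panel of 21 miRNAs, 11 were tested. The other 10, which included the muscle miRNAs miR-1, miR-133a, miR-208b and miR-499a-5p and the blood miRNAs miR-16-5p, miR-126-3p and miR-150-5p, were detected on between 0 and 3 arrays and were not in the main test. Of these, miR-486-3p was called when every deposited probe was tested alone, an alternative chosen after seeing the data, with a difference of 1.03 (adjusted p 0.0368), as was 1 probe of the panel member miR-320e, with 0.82 (adjusted p 0.0368). Besides miR-381-3p, the panel member with the smallest p was miR-1246, at 6.77 ± 1.07 in HCM and 5.72 ± 0.68 in healthy serum, a difference of 1.05 (SE 0.35, p 0.0058, adjusted p 0.516), above the healthy median on 10 of 11 HCM arrays. A second detected probe for miR-1246 gave a difference of -0.03. miR-320e differed by 0.56 (p 0.0114, adjusted p 0.516) and was above the healthy median on 10 of 11 HCM arrays. The remaining panel members had unadjusted p of 0.143 or more. Their differences were -0.90 for miR-451a, -0.56 for miR-29a-3p, -0.56 for miR-223-3p, -0.52 for miR-21-5p, -0.10 for miR-423-5p, -0.01 for miR-320a, 0.02 for miR-122-5p and 0.07 for miR-486-5p. The signs of miR-423-5p, miR-320a, miR-122-5p and miR-486-5p changed with the scaling or the background correction. miR-122-5p was at the floor on 7 HCM and 5 healthy arrays. Between slides 1 and 3, miR-29a-3p went from -1.81 to 0.77 and miR-21-5p from -1.47 to 0.47.

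The list comparisons asked whether sets of miRNAs with a shared source or role shifted against the other tested miRNAs. With camera, 0 of 10 lists passed an adjusted p of 0.05. The DLK1-DIO3 list, from an imprinted miRNA cluster, came closest. Of its 29 names on the array, 22 were detected on no array and 6 were tested, 4 with positive and 2 with negative differences. Its mean difference was 0.17, which was 0.24 above the other miRNAs (camera p 0.0050, adjusted p 0.0501). With an estimated correlation the adjusted p was 0.652 and with slide as a block 0.0810. Tested by fry against no change rather than against the other miRNAs, its adjusted p was 0.464. Of its members, 2 passed when adjusted over the list alone, miR-381-3p (0.00873) and miR-376c-3p (0.0255), against 0 over all miRNAs tested. miR-376c-3p read 3.11 ± 0.83 in HCM and was at the floor on all 12 healthy arrays, a difference of 0.67 (p 0.0085, adjusted p 0.516) whose size is set by the floor. The difference was 1.14 with a lower floor and 0.27 with a higher one. This miRNA was detected on 6 of 11 HCM and 0 of 12 healthy arrays. In the same list miR-494 differed by -0.74 (p 0.0286, adjusted p 0.640) and miR-409-3p by 0.22. After normexp the list was at -0.04 relative to the other miRNAs, with miR-381-3p, miR-376c-3p and miR-409-3p reversed, and with the 75th percentile over all probes or quantile normalization it passed the threshold (adjusted p 0.0290 and 0.0470). Neither call held with an estimated correlation (adjusted p 0.462 and 0.561). Of 23 fits that each left out 1 array, the list passed in 11 at the fixed correlation, and in 0 of these with an estimated one.

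All 5 members of the miR-320 list were tested, and its mean difference of 0.18 was 0.26 above the other miRNAs (adjusted p 0.0696, and 0.840 with an estimated correlation). Its members miR-320b, miR-320c and miR-320d differed by 0.12, 0.12 and 0.13. The list passed with the 75th percentile over all probes (adjusted p 0.0290) and after normexp (adjusted p 9.3e-06), but in neither case with an estimated correlation (adjusted p 0.462 and 0.0630). The 20 GC-rich or fragment-prone names had a mean difference of 0.04, which was 0.12 above the others (adjusted p 0.264, and 0.840 with an estimated correlation). After normexp its adjusted p was 1.54e-07, and 0.0630 with an estimated correlation. Besides miR-1246, the smallest p among them belonged to miR-4466 at 0.39, miR-762 at -0.39 and miR-1207-5p at -0.18.

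The remaining lists had adjusted p of 0.264 or more. The leukocyte list had a mean difference of -0.34 over 7 tested members, which was -0.27 relative to the other miRNAs (adjusted p 0.264). All 7 were negative, including miR-181a-5p at -0.37 and miR-181b-5p at -0.25, which without scaling between arrays were positive. For the fibrosis list the mean difference was -0.42 over 7 members, 6 of them negative (-0.35 relative to the others, adjusted p 0.424). Its members miR-29b-3p, miR-30a-5p and miR-30e-5p differed by -0.91, 0.39 and -0.37, the last positive without scaling. miR-29b-3p was at the floor on 6 HCM and 3 healthy arrays, and its difference was -2.07, -0.54 and -0.22 on slides 1, 2 and 3. Relative to the others the fibrosis list was at -1.07 on slide 1 and 0.29 on slide 3. Without HCM replicate 10 the fibrosis list was at -0.60 (adjusted p 0.0203) and the leukocyte list at -0.41 (adjusted p 0.0267). With an estimated correlation neither passed (adjusted p 0.325 each). The circulating heart failure and hypertrophy list had a mean difference of -0.22 over 9 members, 8 of them negative (-0.14 relative to the others, adjusted p 0.434). Within this list miR-622 was at -0.23 and miR-155-5p, at the floor on 9 HCM and 9 healthy arrays, at -0.15. On slide 3 alone this list was at 0.19 relative to the others, the leukocyte list at 0.12 and the platelet list at 0.22. The 6 tested platelet names had a mean of -0.17 (-0.10 relative to the others, adjusted p 0.751), with miR-151a-3p at -0.27 and miR-197-3p at 0.16. The 3 endothelium and vessel wall names had a mean of -0.15 (-0.08 relative to the others, adjusted p 0.725), with miR-222-3p at -0.45, miR-221-3p at -0.28 and miR-145-5p at 0.27. Without scaling or after normexp this list lay above the others. The 6 red cell names had a mean of -0.10 and a median of 0.04, and the test pointed up although the mean lay at -0.02 relative to the others (adjusted p 0.700) and above them without scaling or after normexp. Their members miR-144-3p, miR-106b-5p and miR-25-3p differed by 0.41, -0.30 and 0.14. The 4 names of the miR-17 clusters had a mean of -0.05 and a median of -0.02, yet lay 0.02 above the others (adjusted p 0.725) and below them after quantile normalization. Among them miR-19b-3p, at the floor on 6 HCM and 6 healthy arrays, was at -0.05 and miR-92a-3p at 0.01. In these lists and the 2 before them, 0 members passed when adjusted over the list alone, and 0 passed over all miRNAs tested. The myomiR list had 1 of 7 names tested, the liver list 1 of 7 and the let-7 list 2 of 9, too few for a list test.

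**Figure D4:**
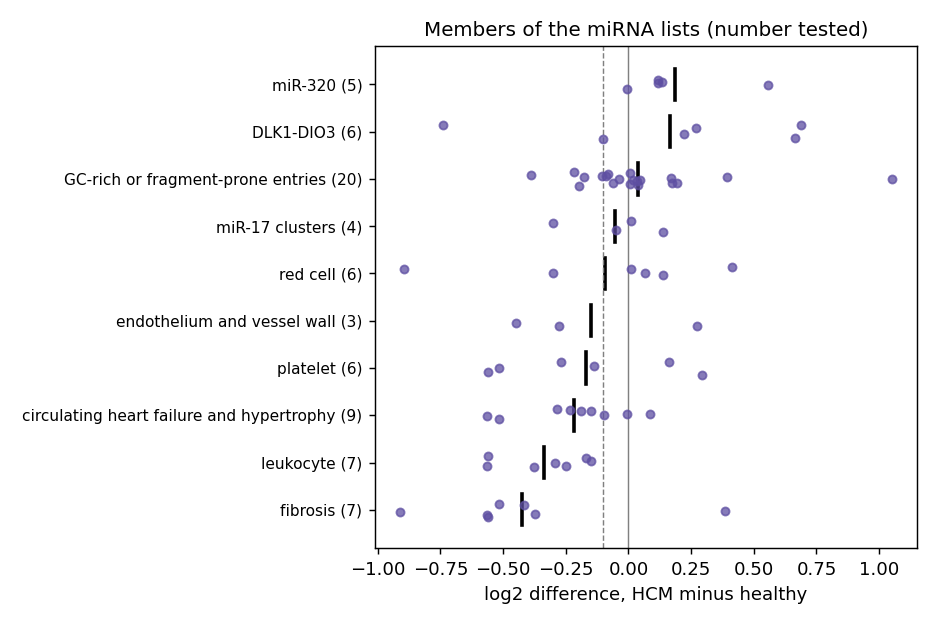
Difference of each tested member (log2, HCM minus healthy) of 10 miRNA lists, with a bar at each list's mean, a solid line at 0 and a dashed line at the median of all tested miRNAs, -0.10. The DLK1-DIO3 members lie on both sides of 0, and after normexp the DLK1-DIO3 mean fell below that of the other miRNAs while the red cell mean lay above it.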

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

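Of the alternatives reported here, the covariate for array signal, the fit without the 4 arrays that detected fewest miRNAs, the Fisher's exact test, every deposited probe alone, human names only, slide as a block for the array measures and the estimated correlation for list calls of other alternatives were chosen after seeing the data. Of 18 alternatives chosen before, 5 called any miRNA at an adjusted p of 0.05, and of the 5 chosen later, 1 did. All calls were higher in HCM. The deposited values and the total gene signal each called 4 miRNAs, slide 2 alone called 2, the lower floor and the rank test each called 1, and every deposited probe alone called 13 of 1750 probes, which carry 7 names, miR-5700, miR-513a-3p, miR-4751, miR-381-3p, miR-376c-3p, miR-320e and miR-486-3p. There the panel members miR-320e and miR-486-3p, each by 1 probe, differed by 0.82 and 1.03 (adjusted p 0.0368 each), and miR-486-3p was detected on 1 of 23 arrays. The lowest adjusted p over these alternatives ran from 0.00863 to 1, against 0.238 in the main values. The lower floor let values of miR-381-3p spread further below the main floor, and its difference was 1.18 in place of 0.69. For the other calls the cause was not tested. The 23 fits that each left out 1 array made 0 calls, with a lowest adjusted p between 0.0677 and 0.503 and between 26 and 43 miRNAs at an unadjusted p under 0.05.

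The count at an unadjusted p under 0.05 moved from 36 to 17 with the filter for detection on all arrays, 11 on slide 1, 20 on slide 3, 69 with array quality weights, 17 with the Fisher's exact test and 112 with every deposited probe. Slide 2 alone gave 37. The first filter tested fewer miRNAs (270), and the deposited table tested more probes. For the slides, the array weights and the Fisher's exact test the cause was not tested. The directions at that p depended on the scaling and on other choices. They were 20 higher and 16 lower in the main values, 22 and 9 with the 75th percentile over all probes, 27 and 6 after quantile normalization, 38 and 0 without scaling, 10 and 21 after normexp, and 38 and 3 in the deposited values. The higher floor gave 13 and 21, array quality weights 22 and 47, the covariate for array signal 17 and 25, and the Fisher's exact test 17 and 0. The median difference of all tested miRNAs was 0.22 without scaling, -0.27 after normexp, 0.02 in the deposited values and -0.03 after quantile normalization, against -0.10 in the main values.

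Without scaling, the brighter HCM arrays (log2 75th percentile 8.22 against 7.80) lifted every value above the floor by construction. The reversed differences were miR-4515 (0.082), miR-423-5p (0.32), miR-320a (0.41), miR-30e-5p (0.046), miR-106b-5p (0.12), miR-151a-3p (0.15), miR-181b-5p (0.21), miR-181a-5p (0.045), miR-222-3p (0.079), miR-221-3p (0.20), miR-19b-3p (0.24), miR-762 (0.031) and miR-1207-5p (0.24). The red cell list (0.076) and the endothelium and vessel wall list (0.074) reversed too; list values are the mean minus that of the other miRNAs. After normexp, the offset of 50 was scaled with each array, so by construction dim names followed the array's brightness in reverse. There miR-5700 (-0.12), miR-381-3p (-0.15), miR-4751 (-0.18), miR-122-5p (-0.094), miR-197-3p (-0.24), miR-376c-3p (-0.13) and miR-409-3p (-0.26) reversed, as did the DLK1-DIO3 list (-0.038), the endothelium and vessel wall list (0.097) and the red cell list (0.18, adjusted p 0.0130, and 0.545 with an estimated correlation). The miR-320 list at 0.38 (adjusted p 9.3e-06) and the GC-rich or fragment-prone list at 0.26 (adjusted p 1.54e-07) passed at the fixed correlation of 0.01. With an estimated correlation neither passed (adjusted p 0.0630 each).

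With the 75th percentile over all probes, the DLK1-DIO3 list at 0.23 and the miR-320 list at 0.27 passed at the fixed correlation (adjusted p 0.0290 each) but not with an estimated one (0.462 each). There miR-320a (0.069) and miR-19b-3p (0.010) reversed. After quantile normalization DLK1-DIO3 passed at 0.24 at the fixed correlation (adjusted p 0.0470, and 0.561 with an estimated one), and the miR-17 clusters (-0.021), miR-320a (0.048) and miR-486-5p (-0.053) reversed. With detection on all arrays DLK1-DIO3 was at -0.12, since 3 of its 6 members, among them miR-381-3p and miR-376c-3p, were then not tested. The deposited values reversed miR-423-5p (0.062) and miR-320a (0.15). The lower floor reversed miR-122-5p (-0.094), and the total gene signal reversed miR-122-5p (-0.20), miR-622 (0.19) and miR-19b-3p (0.096). The higher floor and the mean of probes reversed miR-19b-3p (0.031 and 0.025). Array weights reversed miR-122-5p (-0.14) and miR-320a (0.041), and the rank test did the same for their mean ranks (-2.004 and 0.87). Without the 4 arrays, miR-106b-5p (0.022), miR-19b-3p (0.11) and the red cell (0.15), platelet (0.048) and endothelium and vessel wall (0.017) lists reversed. For the reversals in this paragraph, apart from that of DLK1-DIO3, the cause was not tested.

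On slide 1 alone, fibrosis at -1.07 (adjusted p 0.00236) and DLK1-DIO3 at 0.56 (adjusted p 0.00483) passed at the fixed correlation but not with an estimated one (adjusted p 0.488 each), and the miR-17 clusters (-0.58) reversed. Single reversals there were miR-122-5p (-0.21), miR-423-5p (0.069), miR-320a (0.12), miR-155-5p (0.068), miR-144-3p (-0.52), miR-25-3p (-0.43), miR-197-3p (-0.20), miR-145-5p (-0.42), miR-92a-3p (-0.26), miR-320d (-0.24), miR-320b (-0.16), miR-4466 (-0.22), miR-762 (0.083) and miR-1207-5p (0.013). On slide 2 alone, the GC-rich or fragment-prone list passed at 0.29 at the fixed correlation (adjusted p 0.0268, and 0.765 with an estimated one). The red cell (0.53), endothelium and vessel wall (0.043) and DLK1-DIO3 (-0.0028) lists reversed, with miR-122-5p (-0.82), miR-106b-5p (0.43), miR-19b-3p (0.035) and miR-320c (-0.029). On slide 3 alone, the circulating heart failure and hypertrophy (0.19), fibrosis (0.29), platelet (0.22), leukocyte (0.12), endothelium and vessel wall (0.27), miR-17 clusters (-0.028) and GC-rich or fragment-prone (-0.091) lists reversed. So did miR-21-5p (0.47), miR-29a-3p (0.77), miR-486-5p (-0.66), miR-25-3p (-0.26), miR-197-3p (-0.20), miR-221-3p (0.11), miR-19b-3p (0.29), miR-92a-3p (-0.21), the negative control spots (-0.065) and the labelling spike (0.37). The cause of these slide differences was not tested.

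Leaving out 1 array moved the DLK1-DIO3 list between 0.17 and 0.29 and, at the fixed correlation, past the threshold in 11 fits. With an estimated correlation it passed in 0 of these 11 (adjusted p between 0.325 and 0.656). At the fixed correlation the adjusted p was 0.0194 without HCM replicate 2, 0.0196 without 6, 0.0150 without 7, 0.0401 without 8, 0.0375 without 9 and 0.0267 without 10. Without healthy replicates 14, 17, 18, 19 and 21 it was 0.0312, 0.0317, 0.0197, 0.0160 and 0.0188. The miR-320 list ran from 0.17 to 0.35 and passed in 6 fits, without HCM replicates 2 (adjusted p 0.0194), 7 (0.0395), 9 (0.0375) and 12 (0.0250) and healthy replicates 19 (0.0121) and 21 (0.0151). With an estimated correlation it passed in 0 of these 6 (adjusted p between 0.356 and 0.763). Without HCM replicate 10 the fibrosis list passed at -0.60 (adjusted p 0.0203) and the leukocyte list at -0.41 (adjusted p 0.0267), but not with an estimated correlation (adjusted p 0.325 each), and their other ends were -0.21 and -0.19. Lists near 0 changed sign and passed in no such fit. The red cell list ran from -0.19 to 0.16 (9 reversals, without HCM replicates 1, 2, 7, 9 and 11 and healthy replicates 16, 17, 19 and 22), platelet from -0.25 to 0.046 (2, HCM replicate 2 and healthy replicate 16), endothelium and vessel wall from -0.24 to 0.077 (3, HCM replicates 2 and 7 and healthy replicate 26) and the miR-17 clusters from -0.17 to 0.22 (10, HCM replicates 1, 6, 8, 10 and 12 and healthy replicates 15, 18, 20, 23 and 25). Single miRNAs near 0 did so too, with ranges of -0.45 to 0.24 for miR-122-5p, -0.18 to 0.023 for miR-423-5p, -0.11 to 0.11 for miR-320a, -0.0998 to 0.23 for miR-486-5p, -0.020 to 0.29 for miR-25-3p, -0.43 to 0.36 for miR-19b-3p, -0.17 to 0.15 for miR-92a-3p and -0.014 to 0.22 for miR-320b. The arrays whose absence reversed them were HCM 7 and 12 for miR-423-5p, HCM 6 and healthy 15 for miR-25-3p, and HCM 8 for miR-320b. For miR-486-5p they were HCM 5, 6 and 8 and healthy 15, 20 and 23, and for miR-122-5p HCM 1, 10 and 12 and healthy 14, 15, 18, 19, 21, 25 and 26. For miR-320a they were HCM 2, 7, 9 and 12 and healthy 14, 18, 19 and 21, for miR-19b-3p HCM 2, 3, 5, 6, 7, 9 and 11 and healthy 16 and 22, and for miR-92a-3p HCM 1, 3, 5, 6, 8 and 10 and healthy 15, 18, 20, 23, 25 and 26. Larger differences kept their sign but moved, from -1.24 to -0.36 for miR-451a, -0.69 to -0.29 for miR-223-3p, -0.69 to -0.26 for miR-21-5p and -0.88 to -0.38 for miR-29a-3p. The cause was not tested.

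The values of miR-513a-3p, kshv-miR-K12-10b, miR-1246, miR-320e, miR-30a-5p, miR-4644, miR-205-5p, miR-4476, miR-3680-3p, miR-494, miR-451a, miR-223-3p and miR-29b-3p kept their direction under each of the alternatives run on them. Apart from leave-one-out fits and the rank test, miR-513a-3p ran from 0.40 to 1.92, miR-1246 from 0.35 to 1.53, miR-320e from 0.11 to 0.98 and miR-205-5p from -1.61 to -0.39. Of the 28 list calls that alternatives made at the fixed correlation, 0 held with an estimated one. In all, 790 values of single miRNAs, 312 of lists and 31 of array measures kept both direction and side of the threshold. Against these, 72 values of single miRNAs, 46 of lists and 2 of array measures changed sign. A further 12 of single miRNAs and 27 of lists kept their sign and passed the threshold. The main values made no call, so keeping the side meant staying short of the threshold. Signal over background limits the comparison: 18.6% of probe values were detected, 10 of the 21 panel miRNAs fell under the detection filter of the main test, and differences of names near the floor depend on where the floor lies. The planned restriction to miRNAs found in the cat genome was not run, since no cat genome was used here. No paired analysis was possible because the groups share no replicate numbers.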

Other observations

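Tests on the co-varying names, the corner spots among them, on the viral names and the miR-320 family, and the splits of the main count and within slides were chosen after the result was seen. The other splits of the count at an unadjusted p and of the deposited values were not. In 100 splits of the 23 arrays into groups of 11 and 12, the real one included, 100 gave at least the 0 calls of the real groups, which could not come out otherwise and so tests nothing. The highest of the other splits gave 62 calls, and 2 splits made any call. A split with that many calls may point to a structure among the samples other than their group, which was not tested. For the 36 miRNAs at an unadjusted p under 0.05, 29 of 100 splits gave as many, with a highest other of 107, so chance cannot be excluded for that count. For the 4 miRNAs called in the deposited values, 1 of 100 splits, the real one, gave as many, and the highest other gave 3. In 100 splits that kept each slide's group sizes, 1 gave as many, again the real one, and the highest other gave 2. At this number of splits, none of the others reached that count, which makes it uncommon but does not exclude chance. The deposited values were 1 of 23 alternatives, of which 6 made any call, and the splits do not allow for that choice. The result says nothing about the row of the slide, which divides the arrays exactly as the groups do.

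Of the names higher in HCM, miR-5700, miR-513a-3p, miR-4751 and miR-320e had a mean difference of 0.78 on the log2 scale. They ranked 1, 3, 4 and 12 by p and were picked after the result was seen, by no fixed rule. Left out of this set were miR-381-3p, kshv-miR-K12-10b, miR-1246 and miR-376c-3p, also higher in HCM, with ranks 2, 5, 6 and 7. With group means removed and n = 23, Pearson's r was 0.88 for miR-5700 with miR-513a-3p (Spearman's rho 0.90), 0.92 for miR-5700 with miR-4751 (rho 0.89) and 0.72 for miR-513a-3p with miR-4751 (rho 0.75). Each permutation p was 1e-05, the smallest that 100000 resamples can give, and 3e-05 after adjustment over the 9 pairs computed. That adjustment does not allow for the choice of the names. Without the 2 arrays farthest from the median of the first name, r was 0.82, 0.89 and 0.62. Within slides 1, 2 and 3, r was 0.97, 0.73 and 0.83 for the first pair, 0.91, 0.95 and 0.97 for the second and 0.80, 0.64 and 0.74 for the third. For miR-4751, every healthy array of slides 2 and 3 was at the floor of 2.45. The r of its pairs on these slides thus rest on the 4 HCM arrays of each. In all, 10 of 12 healthy and 3 of 11 HCM arrays were at the floor for miR-4751, which also limits its r at n = 23. Over all 147153 pairs of tested miRNAs the median r was 0.015, and 2.08% reached 0.8. The pairs with miR-320e were weaker, with r of 0.47 (rho 0.51, permutation p 0.0239, adjusted 0.0307), 0.40 (rho 0.41, permutation p 0.0666, adjusted 0.0666) and 0.41 (rho 0.45, permutation p 0.0530, adjusted 0.0597), and of 0.40, 0.30 and 0.40 without the 2 arrays farthest from the median.

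The main values were already scaled to the 75th percentile signal of the array. A covariate for that signal tests only what the scaling left, and cannot decide whether the signal accounts for these 4 differences. With its log2 value as a covariate, the mean difference of the 4 names was 0.827 (0.407 to 1.25 within 2 standard errors), against 0.779 without it. With the bright corner spots as a covariate it was 0.808, so it did not fall, and their coefficient was -0.033 (SE 0.114). Its range of 0.352 to 1.26 still reached below the limit written down for excluding them. The width of that range decided this and not a fall in the difference. The rule thus could not exclude the brightness of the corner spots, which stays open. A candidate explanation is that 1 RNA in cat serum bound to several of these probes, so that the names would count it more than once. If all 4 probes read 1 RNA alone, every pair was to reach an r of 0.5, and the lowest of the 6 was 0.399. If they shared none, the median r of the 6 pairs was to be under 0.3, and it was 0.598. Neither condition was met, so the idea stays open. Mature sequences and probe sequences were not used here. The row of the slide also stays open and cannot be told apart from the group, since 0 groups had arrays in both rows. A biological difference between cats with HCM and healthy cats remains open as well and was not tested apart from these.

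A further 3 of the 9 pairs involved miR-381-3p, miR-376c-3p and miR-1246, also picked by no fixed rule. With group means removed and n = 23, r was 0.93 for miR-381-3p with miR-376c-3p (rho 0.75, permutation p 0.00036, adjusted 0.00081), 0.61 for miR-381-3p with miR-1246 (rho 0.62, permutation p 0.0055, adjusted 0.0099) and 0.55 for miR-376c-3p with miR-1246 (rho 0.55, permutation p 0.0208, adjusted 0.0307). Without the 2 arrays farthest from the median it was 0.79, 0.52 and 0.38. Within slides 1, 2 and 3 it was 0.9993, 0.90 and 0.94 for the first pair, 0.79, 0.44 and 0.77 for the second and 0.78, 0.11 and 0.77 for the third. All 12 healthy arrays were at the floor for miR-381-3p and miR-376c-3p, so these relations rest on the HCM arrays. Slide 1 held 3 of these, so its r of 0.9993 has little precision. There HCM replicate 2 was at the floor for both names, while replicate 1 read 4.68 and 5.10.

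The arrays carried 139 names of human viruses, which cat serum is not known from the labels to hold. Of these, 39 or 28.1% (95% exact interval 20.8 to 36.3) were detected on at least 6 arrays, beside 26.7% of 1887 human names (Fisher's exact p 0.766). A total of 19 viral names, from 7 viruses, were detected on all arrays. Among human names, the share was 27.5% for those numbered under 500 and 28.9% for those numbered 1000 or higher (Fisher's exact p 0.623). These shares are consistent with probe signal that is not specific to the named miRNA, and this may hold for human names too. The test cannot separate RNA that matches a probe in part from RNA that binds for other reasons. No biological explanation was tested.

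The log2 value of miR-320e minus the mean of miR-320a to miR-320d was 0.34 ± 0.25 in HCM (SD, n = 11) and -0.12 ± 0.37 in healthy serum (SD, n = 12), a difference of 0.47 with a permutation p of 0.00209. Within slides the difference was 0.097 on slide 1 (exact permutation p 0.571), 0.75 on slide 2 (exact permutation p 0.0286) and 0.54 on slide 3 (exact permutation p 0.0857). Scaling between arrays cancels in this measure where no value is at the floor. The family member was picked because of its difference, so the p is not independent evidence. No more than a hypothesis of unequal change follows, and nothing on whether miR-320a to miR-320d changed. Whether miR-320e shares a signal with miR-5700 stays open, as do the row of the slide and a biological difference between the groups.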
